A study of Mus musculus with 4 samples.

How the data were processed

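Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding of the transcription factor Foxo1 in mouse CD8+ T cells. Of the 4 samples, 1 was a pull-down with a Foxo1 antibody from wild-type cells and 1 was a streptavidin pull-down from Foxo1tagBirA cells, in which the cells themselves attach biotin to Foxo1. The other samples were the sequenced input DNA of each genotype. Each of these 4 groups had 1 library, and groups were taken from the labels. With no replicate of either pull-down, no spread between libraries could be estimated, and every p-value below concerns the peaks or positions in these lists, not the pull-downs as repeated experiments.

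The reads were not used here, and the analysis started from 3 peak lists as the authors deposited them. Per the submitters' processing notes, CASAVA 1.4, Bowtie 0.12.7, MACS and the mouse build mm9 were used. These notes give no role or order, and the version of MACS and the peak-calling settings are not given in the sources used here. Whether each pull-down was set against its own input is likewise not given. Per the file text, the antibody and streptavidin lists hold for each peak an interval, a summit position, a linear fold enrichment and a p-value, all of which are the authors' own. Their deposited file names carry a false discovery rate of 0.05. The largest p-value was 1.00e-08 in the antibody list and 9.96e-09 in the streptavidin list. A p-value of exactly 0 was listed for 512 antibody peaks and 251 streptavidin peaks, so p-values could not rank the strongest peaks and the fold was used as the score. The joint list, filed with the wild-type input sample, holds intervals only, and the rule that made it is not given in the sources used here. Read depth was not recoverable from peak lists and is unknown.

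Peaks in each of the fold-bearing lists were all 300 bp wide and those of the joint list 500 bp. A peak was called shared when at least 1 bp lay in a peak of the other list. The shared count was compared with 1000 random placements of the other list's peaks on their own chromosomes, between the outermost peaks of any list, in a one-sided permutation test whose smallest p is 0.001. Folds of shared and unshared peaks were compared by the difference of medians in a 2-sided permutation test with 100000 resamples, whose smallest p is 1e-05. The probability of superiority is the percentage of pairs of 1 shared and 1 unshared peak in which the shared peak has the higher fold. Correlations over overlapping pairs are across peaks, which are not independent replicates. Shares of a list on a chromosome were compared by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over 22 chromosomes. Intervals on percentages are 95% exact Clopper-Pearson intervals and cover counting of peaks only. Pairs in which each peak was used once were formed by nearest midpoints. Coordinates are 1-based and in mm9.

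Peaks named in the text followed a rule fixed before the data were examined: the 10 shared regions with the largest product of fold ranks in both lists (the highest fold taking the largest rank), and the 5 unshared peaks of highest fold in each list. A condition added later kept only the first of named shared regions less than 1000 bp apart. Regions named by other criteria are said to be so. The planned assignment of peaks to genes, the tests of 11 gene lists (naive and memory, effector, FOXO target, T cell identity, other lymphoid Foxo1 target, phosphoinositide 3-kinase pathway, FOXO family, B cell, myeloid, other tissue and housekeeping genes), the distance to transcription starts and the search for the forkhead motif were not run. They need the sequence or annotation of mm9, and the gene table used here is of GRCm38. On chromosome 1, 3 antibody peaks and 3 streptavidin peaks lie beyond the last gene of that table, so its coordinates could not be used with these lists. No gene is therefore assigned to a peak.

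Alternatives fixed before the data were examined were a minimum overlap of 50% of a peak, midpoints within 200 bp, the peaks above the median fold of their list, the 1000 peaks of highest fold, shifts of 20 to 500 kb in place of random placement, and numbered chromosomes only. Further ones were removal of the 1% highest folds for the comparison of folds and of the 5% highest folds of either list for the correlation. Analyses added only after the data had been examined were the shared percentage by fold quintile and among the top 100 peaks, the distances between summits and midpoints, the fold ratio of pairs, the folds of shared peaks inside and outside the joint list, the shared percentage of each chromosome against the others, and the folds on chromosome X. Their p-values do not allow for this choice. The scripts were tested on simulated lists of the real sizes. With 499 overlaps planted, the overlap count for the antibody list against the streptavidin list was 504 where 5.05 were expected by chance. With none planted, 3 of 50 simulated pairs of lists gave a placement p under 0.05. Simulated positions were drawn at random as in the placement test itself, without the crowding of the real lists, and with fewer placements. These runs check the scripts and not how the test behaves on crowded peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.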

Results

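Foxo1 is a forkhead transcription factor that leaves the nucleus when phosphorylated by the kinase Akt downstream of phosphoinositide 3-kinase. In T cells it is known for its part in the homing and survival programmes of naive and memory cells, and the series concerns its role in memory CD8+ T cell responses to infection. Its binding sites in CD8+ T cells were mapped in parallel by an antibody against the native protein in wild-type C57BL/6 cells and by streptavidin in cells of Foxo1tagBirA mice. In the latter, a tag on the endogenous Foxo1 is biotinylated by BirA, a bacterial biotin ligase, so that the protein can be captured without an antibody. Each pull-down and each matching input was sequenced as 1 library. Error between libraries therefore could not be estimated, and read depth is unknown.

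The antibody pull-down gave the longer list and the higher enrichment. It held 4868 peaks covering 1441 kb, with a median fold enrichment of 3.41 (quartiles 2.49 and 5.05), whereas the streptavidin list held 3732 peaks covering 1105 kb, with a median fold of 2.59 (quartiles 1.99 and 3.41). Folds above 10 were listed for 284 antibody peaks (5.83%) and 37 streptavidin peaks (0.991%). At the other end, 144 antibody peaks (2.96%) and 271 streptavidin peaks (7.26%) had a fold below 1.5. In the antibody list 622 peaks (12.8%) lay less than 1000 bp from another peak of the same list, and in the streptavidin list 393 did (10.5%). The lists were called on different libraries with their own depth and background, so the difference in length and fold was not tested.

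The first comparison asked how far the antibody and the biotin tag located Foxo1 at the same sites. A minority of each list was found by both methods. Of the 4868 antibody peaks, 1062 (21.8%, 95% interval 20.7 to 23.0%) overlapped a streptavidin peak. Of the 3732 streptavidin peaks, 1054 (28.2%, 95% interval 26.8 to 29.7%) overlapped an antibody peak. Random placement of the streptavidin peaks gave a mean of 4.97 overlapping antibody peaks (SD 2.15 over 1000 placements) and at most 12. Random placement of the antibody peaks gave a mean of 5.03 overlapping streptavidin peaks and at most 13. The observed overlap was 214 and 209 times these means (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Shifts of 20 to 500 kb, which keep regional density, gave means of 8.411 and 8.410 and an overlap 126 and 125 times as large (permutation p = 0.001 for each). Most peaks of either list, 3806 antibody and 2678 streptavidin peaks, had no overlapping partner at the authors' threshold.

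At the shared sites, the peak summits of both methods lay close together. The 1137 overlapping pairs reduced to 992 pairs when each peak was used once, and their summits lay a median of 30.5 bp apart (quartiles 12 and 66 bp). Summits were within 50 bp of each other in 656 pairs (66.1%). The midpoints of the intervals lay a median of 28 bp apart and within 50 bp in 70.7% of pairs. Overlaps arising from random placement had a median midpoint distance of 148 bp, with 18.0% within 50 bp.

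**Figure D1:**
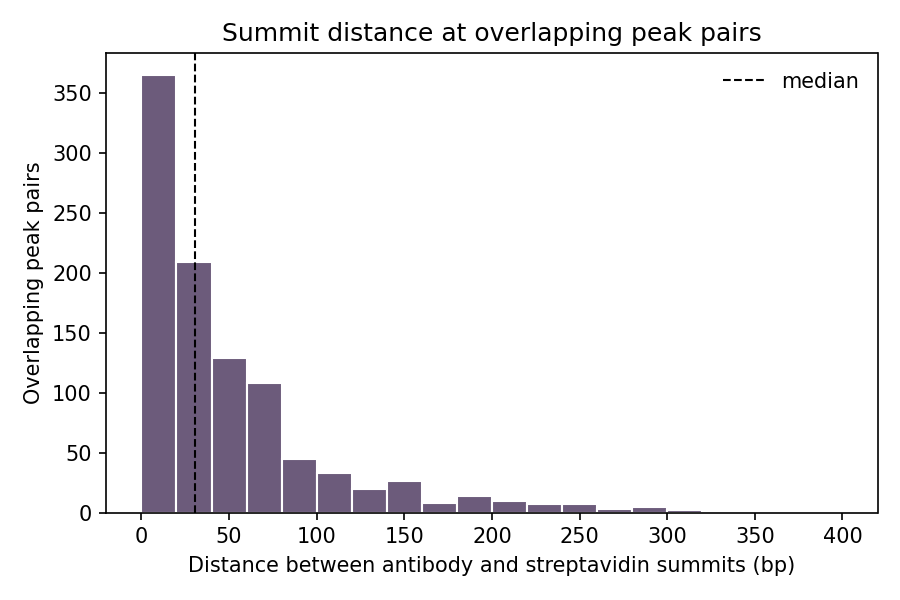
Histogram of the distance in bp between the antibody summit and the streptavidin summit (x axis) against the number of overlapping peak pairs (y axis), for the 992 pairs in which each peak was used once. The dashed line marks the median of 30.5 bp, and the counts fall off with distance.

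Sites found by both methods were the more strongly enriched ones in each list. The median fold of shared antibody peaks was 5.31 (quartiles 3.64 and 8.56) and that of unshared antibody peaks 3.08 (2.35 and 4.34), a difference of 2.23. Shared streptavidin peaks had a median fold of 3.33 (2.34 and 4.83) and unshared ones 2.44 (1.89 and 3.03), a difference of 0.889. Both differences exceeded all 100000 resamples of a 2-sided permutation test over peaks (p = 1e-05, the smallest it can give). A shared peak had the higher fold in 75.7% of pairs of a shared and an unshared peak in the antibody list and in 70.4% in the streptavidin list. By fold quintile of the antibody list, the shared percentage was 7.08% in the lowest quintile (95% interval 5.55 to 8.88%), 16.0% in the middle quintile and 50.7% (47.5 to 53.9%) in the highest. By quintile of the streptavidin list it was 14.6% (12.1 to 17.3%) in the lowest, 17.2% in the middle and 59.4% (55.8 to 63.0%) in the highest. In the streptavidin list the rise was not even, because the next to lowest quintile, at 21.2% (18.3 to 24.3%), lay above the middle one. Among the 100 peaks of highest fold, 73 antibody peaks and 77 streptavidin peaks were shared, which left 27 and 23 of these without an overlapping peak in the other list.

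**Figure D2:**
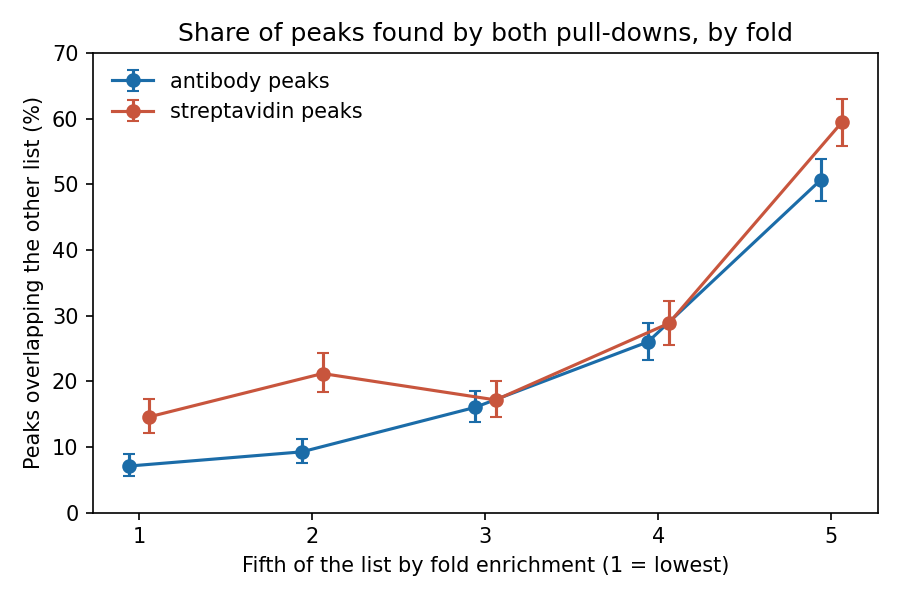
Percentage of peaks overlapping the other list (y axis) in each quintile of a list ordered by the authors' fold enrichment (x axis, 1 the lowest), for antibody (blue) and streptavidin (red) peaks, with 95% exact binomial intervals. The percentage goes from 7.08% to 50.7% in the antibody list and from 14.6% to 59.4% in the streptavidin list.

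The fold of a site in one pull-down was related to its fold in the other. Over the 1137 overlapping pairs, Spearman's rho was 0.36 and Pearson's r was 0.55 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). These correlations are across peaks of 1 library per method. Without the pairs in the 5% highest folds of either list, r was 0.33 and rho 0.27. The antibody fold was the higher of the 2 at 785 of the 992 single-use pairs (79.1%), with a median ratio of antibody to streptavidin fold of 1.71 (quartiles 1.11 and 2.52).

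**Figure D3:**
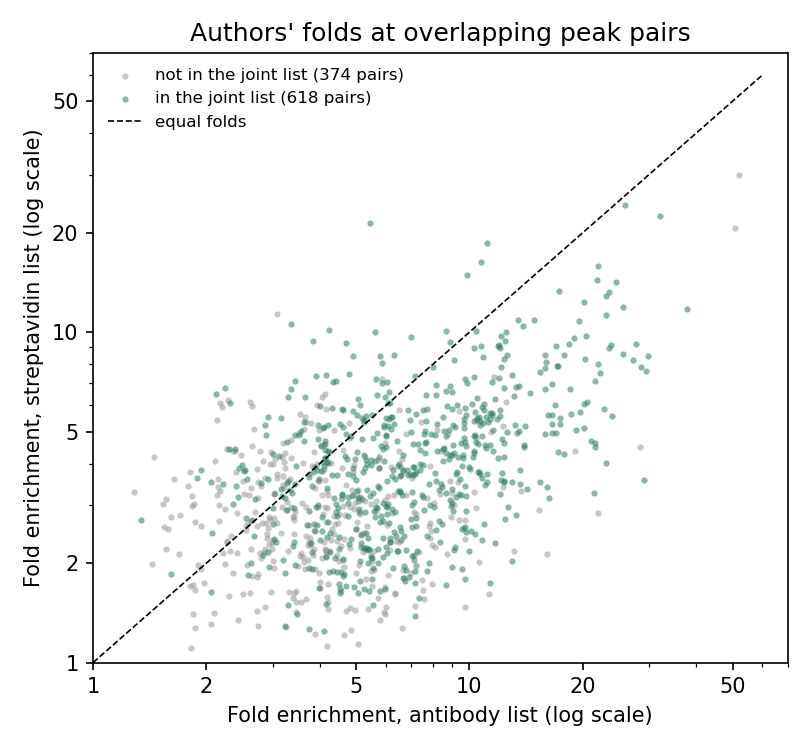
Authors' fold enrichment in the antibody list (x axis, log scale) and in the streptavidin list (y axis, log scale) for the 992 overlapping pairs in which each peak was used once. Green points lie in the deposited joint list and grey points do not, and 79.1% of points lie below the dashed line of equal folds.

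The regions ranked highest by both methods were spread over 8 chromosomes. The first was on chromosome 17, where the antibody peak at 39985273 to 39985572 had a fold of 52.0 and the streptavidin peak at 39985486 to 39985785 a fold of 29.9. Here the summits lay 286 bp apart, the widest gap among the named regions. The second was on chromosome 11, where the antibody peak at 108873123 to 108873422 had a fold of 50.8 and its streptavidin partner a fold of 20.6, with summits 82 bp apart. Among the named regions, the authors' p-value was largest on chromosome 17 in the antibody list (1.51e-13). In the streptavidin list it was largest on chromosome 11 (6.31e-11). Whether repeated or misassembled sequence underlies either region was not tested. At the other named regions the summits lay 1 to 28 bp apart. Chromosome 4 held 2 of them. Its peak at 33334744 to 33335043 had folds of 32.0 with the antibody and 22.4 with streptavidin, and summits 1 bp apart. Its peak at 32430758 to 32431057 had folds of 24.5 and 14.2. On chromosome 14, the peak at 8930515 to 8930814 stood out for nearly equal folds, 25.9 with the antibody and 24.2 with streptavidin. On chromosome 2, the peak at 19579220 to 19579519 had folds of 37.9 and 11.7. Chromosome 8 also held 2, at 87502630 to 87502929 with folds of 23.5 and 13.3 and at 13686443 to 13686742 with folds of 23.1 and 12.9. The peak on chromosome 9 at 45763196 to 45763495 had folds of 25.5 and 11.9, and that on chromosome 16 at 91533787 to 91534086 folds of 21.98 and 15.8. No gene is assigned to these positions here, because annotation of mm9 was not used.

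The strongest sites of one method without an overlapping partner were of different kinds. The antibody peak of highest fold in the whole list, 56.2 on chromosome 17 at 39982153 to 39982452, was unshared but lay 3333 bp from the nearest streptavidin midpoint, in the same part of the chromosome as the top shared region. The other 4 antibody peaks were isolated from any streptavidin peak by over 50 kb. They were on chromosome 2 at 24775064 to 24775363 (fold 43.1), chromosome 8 at 72758250 to 72758549 (29.5), chromosome 4 at 154937768 to 154938067 (26.1) and chromosome 18 at 80403377 to 80403676 (25.8). Of the 5 unshared streptavidin peaks, that on chromosome 3 at 5860576 to 5860875 (fold 14.7) lay 267731 bp from the nearest antibody midpoint. The other 4 had an antibody peak nearby that they did not overlap. The peaks on chromosome 11 at 51813808 to 51814107 (13.7), chromosome 2 at 167602895 to 167603194 (12.4), the mitochondrial genome at 15861 to 16160 (12.1) and chromosome 16 at 91534735 to 91535034 (12.02) had an antibody midpoint 381, 530, 426 and 948 bp away. Those on chromosomes 11, 2 and 16 also had another streptavidin midpoint 351, 566 and 976 bp away. The antibody peak near the one on chromosome 16 was that of the named shared region there. Whether repeated or misassembled sequence underlies any of these unshared peaks was not tested.

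A further deposited list, called the joint list here, held 613 intervals and corresponded to a stronger subset of the sites seen by both methods. All 613 intervals overlapped at least 1 antibody peak and at least 1 streptavidin peak, although the list is filed with the wild-type input sample. Its deposited name joins both pull-downs, so this overlap may be built in and is no independent evidence. The list covered 666 of the 1062 shared antibody peaks (62.7%) and 668 of the 1054 shared streptavidin peaks (63.4%), which left out 396 and 386. The shared antibody peaks it covered had a median fold of 6.42 and those it left out 3.94, a difference of 2.47. For shared streptavidin peaks the medians were 3.87 and 2.70, a difference of 1.16 (2-sided permutation p = 1e-05 for both, the smallest the resamples can give). It also touched 16 antibody and 20 streptavidin peaks that did not overlap a peak of the other list. Of the 10 named shared regions, the list held all but the top regions on chromosomes 17 and 11. It had no interval on chromosome Y or the mitochondrial genome. The streptavidin peak on chromosome 11 at 51813808 to 51814107 was the only unshared named peak within it.

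The X chromosome stood apart in how rarely its peaks were found by both methods. No chromosome passed the adjusted threshold between the lists by Fisher's exact test over 22 chromosomes, and 4 had an unadjusted p under 0.05. The lowest was X, with 232 antibody peaks (4.77%, 95% interval 4.184 to 5.402%) and 130 streptavidin peaks (3.48%, 2.92 to 4.12%; exact p = 0.0034, adjusted p = 0.075). Of the antibody peaks on X, 19 were shared (8.19%, 95% interval 5.003 to 12.49%), against 22.5% of the peaks elsewhere (exact adjusted p = 4.43e-07). It was the only chromosome of the antibody list past the adjusted threshold; the comparison of shared percentages between chromosomes was added after the lists had been examined. Of the streptavidin peaks on X, 16 were shared (12.3%), against 28.8% elsewhere (exact adjusted p = 0.00035). Peaks on X also had lower folds. The median was 2.02 for antibody peaks on X and 3.49 on the numbered chromosomes, and 2.01 and 2.61 for streptavidin peaks (2-sided permutation p = 1e-05 for both, the smallest the resamples can give). Among peaks above the median fold of their list, 9 of 29 antibody peaks on X (31.03%) and 10 of 33 streptavidin peaks on X (30.3%) were shared, against 34.3% and 39.2% on the other chromosomes (Fisher's exact p = 0.84 and 0.37). With so few peaks on X these tests do not show that the percentages were alike. In the streptavidin list chromosome 11 lay above the rest, with 87 of 221 peaks shared (39.4%, Fisher's exact adjusted p = 0.0030). Its streptavidin peaks also had the highest median fold of the numbered chromosomes, 2.84. Whether fold accounts for the higher shared percentage of chromosome 11 was not tested. In the antibody list 25.7% of its 339 peaks were shared (Fisher's exact adjusted p = 0.47). The joint list had 7 of its intervals on X (1.14%, 95% interval 0.460 to 2.34%) and 57 on chromosome 11 (9.30%, 7.12 to 11.9%).

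**Figure D4:**
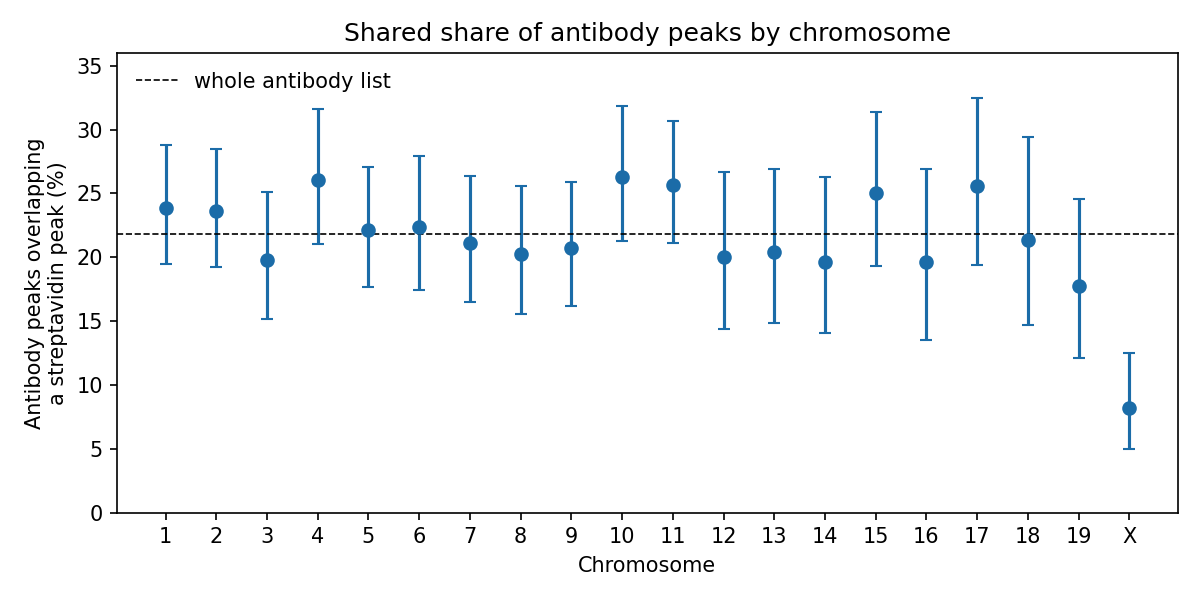
Percentage of antibody peaks that overlap a streptavidin peak (y axis) on each numbered chromosome and on X (x axis), with 95% exact binomial intervals; the dashed line is the 21.8% of the whole antibody list. X lies at 8.19%, with its interval below the line.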

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

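Alternatives that keep 1 peak per local stack, rank peaks by p-value, use each peak once, or concern chromosome X or the coverage of the joint list by 50% of an interval were chosen after the data had been seen, as was the numbered-chromosome alternative for the fold comparison. Of 43 alternative values, 40 kept their direction and their side of the threshold, or stayed within counting error. The shared percentage of antibody peaks ranged from 19.7% with an overlap of 50% of a peak to 33% among the 1000 peaks of highest fold. That of streptavidin peaks ranged from 25.9% to 34.6%. Settings that kept only the peaks of highest fold or smallest p-value cut both lists, so partners outside the cut were not counted. Against the whole streptavidin list, 50.7% of the highest fold quintile of antibody peaks were shared. With shifts of 20 to 500 kb in place of random placement, the overlap was 126 and 125 times the chance mean. An overlap of 50% of the shorter peak and of both peaks is the same rule here, since every peak has the same width, so the 43 hold some values more than once. For the joint list, 0 of 613 intervals were identical to the interval common to both peaks, a consequence of their fixed width of 500 bp, which no such common interval can reach. The low shared percentage on chromosome X was no longer past the threshold among peaks above the median fold. It was 31.03% of 29 antibody peaks and 30.3% of 33 streptavidin peaks. That test kept the other list whole, and fewer peaks enter it. Of the 10 named shared regions, 9 kept an overlap of 50%. Alternatives by peak width were void because width did not vary, and those on motif, transcription start and gene lists were not run for want of mm9 sequence and annotation. Depth is unknown, and with 1 library per method no replicate could be left out.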

Other observations

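The tests on chromosome X and on open chromatin, the thresholds for the joint list and the comparison of fold with p-value were chosen after the data had been seen. Only the tests of regional crowding, stacked peaks and neighbouring loci were written down before their results. Sites seen by both methods tended to lie near each other. After peaks of the antibody list less than 1000 bp apart were counted as 1 locus, 955 of 4545 loci were shared, and 219 of these (22.9%) had another shared locus within 50 kb. In 1000 draws of antibody loci with the same distribution over fold quintiles, the percentage averaged 15.5% and reached at most 19.8%. Shared loci thus lay near each other more often than drawn antibody loci of like fold quintile. The draws were taken from all antibody loci, shared ones included, and were not compared with random spacing. How far a general tendency of antibody loci to crowd contributes therefore cannot be told. The draws were matched neither on chromosome nor on fold within a quintile. Whether differences in these account for the excess over the draws was not tested. With gaps of up to 50 kb, 2 groups held 4 shared loci each, on chromosome 11 from 98997840 to 99032364 (antibody folds 3.91 to 19.7) and on chromosome 8 from 74801276 to 74878593 (folds 4.24 to 10.8). Of the joint list, 4 and 3 intervals overlapped loci of these groups. These groups were picked after their values were seen.

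The overlap of the antibody and streptavidin lists far exceeded chance. Regional crowding of peaks is argued against, because shifts of the streptavidin peaks by 20 to 500 kb left at most 18 overlapping antibody peaks against the 1062 observed. Stacking of peaks is argued against as the whole cause. Of the 4246 antibody peaks with no neighbour within 1000 bp, 746 overlapped such a streptavidin peak, against at most 11 in random placements. Repeated or misassembled sequence under single peaks passes this filter, so the test cannot decide on it. Open chromatin pulled down by both methods without Foxo1 cannot be told apart from Foxo1 binding, since 0 pull-downs came from cells without Foxo1 and 0 streptavidin pull-downs from cells without the tag. Foxo1 binding itself, which the design aims at, stays among the open explanations.

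Peaks on chromosome X were seldom shared and had low folds. A lower fold on chromosome X is a possible explanation of the antibody result, because peaks of other chromosomes matched on fold gave a mean of 25.8 shared (middle 95% of draws 18 to 35) against 19 observed. For the streptavidin list the matched mean was 26.1 (18 to 34) against 16 observed, so the streptavidin fold alone falls short there. The draws were matched only on the fold in the list they came from. Sharing also needs a called peak in the other list, where folds on X were low too. Low folds in both lists together therefore stay possible as the explanation.

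For the low folds themselves, later tests were chosen after the first ones had argued against an explanation, in part with their values known, and they are given with the first ones. More X copies in the pull-down than in its input are argued against as the whole cause only if X holds strong sites as densely as the numbered chromosomes, which is not known. X held 0.0747 antibody peaks of the highest fold quintile per Mb (95% Poisson interval 0.0386 to 0.130, lowest numbered chromosome 0.221) and 0.0435 streptavidin peaks (0.0175 to 0.0897, lowest 0.175). Its density of all peaks, 1.44 and 0.809 per Mb, lay below every numbered chromosome. The later test, which largely restates the low folds and was not used to decide, gave 0.946 antibody peaks of the lowest quintile per Mb on X, above all numbered chromosomes (0.221 to 0.437), but 0.348 streptavidin peaks, inside their range (0.229 to 0.362). A signal on X scaled down by a constant factor is left undecided. The ratio of upper to lower fold quartile on X was 1.42 in the antibody list, outside the 1.76 to 2.16 of the numbered chromosomes, and 1.59 in the streptavidin list, inside 1.53 to 1.95. Scaled-down peaks that fail the calling threshold leave the list, so this ratio need not be kept and a narrower one does not count against scaling. In the later test the density of strong antibody peaks on X lay within the numbered range above a doubled fold (median 0.0826, range 0.0440 to 0.187). That of streptavidin peaks also lay within its range (median 0.0397, range 0 to 0.101). With a lower end of 0, no density on X could have fallen below the streptavidin range. The sex of the mice was not among the labels used here, fewer strong Foxo1 sites on X stay open, and no biological explanation was tested.

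No single value separated the shared pairs in the joint list from the others. Of 6 values tried on the same pairs, the best threshold, on the antibody p-value, placed 72.4% of the 992 pairs correctly, against 62.3% when every pair was placed in the list. The 2 shared regions with the largest product of fold ranks were outside the list.

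Fold and p-value ranked peaks alike only in part. Across peaks, Spearman's rho between them was -0.67 in the antibody list and -0.53 in the streptavidin list. The negative sign means that higher folds tended to go with smaller p-values. Peaks with a p-value listed as 0 had folds from 1.498 to 43.1 in the antibody list and from 1.498 to 24.2 in the streptavidin list.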
